A study of Mus musculus with 6 samples.

How the data were processed

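RNA of 32D cells was measured on Affymetrix Mouse Genome 430 2.0 arrays, 1 array per sample, in 3 mock-transduced and 3 Nup98::Nsd1 samples. Per the labels, the authors processed the arrays with MAS5, and per the file headers each deposited signal is a scaled intensity on a linear scale. Beside each intensity the authors deposited a MAS5 detection p-value and a detection call of Present, Marginal or Absent. The MAS5 version, the scaling target and the trimming are not given in the sources used here. The 2% trimmed mean of the signals was 500.003 on every array. The deposited matrix of the series held the same intensity values, with a largest relative difference of 5.0e-06.

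Each array carried 45101 probe sets, of which 64 were controls and were left out of the tests. Of the other 45037, 34945 had 1 gene symbol in the platform annotation of 2016, 932 had several and 9160 were not listed; symbols were updated through the Entrez identifier in a RefSeq table for 34754. Signals under 1 were set to 1 (3183 signals) and taken to log2 with no further scaling. A probe set was tested if it was called Present on all 3 arrays of at least 1 group, which left 20494, 2709 of them without a single symbol. A gene was represented by its tested probe set with the highest mean log2 signal, giving 9641 genes.

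Groups were compared with limma 3.58.1 in R 4.3.3, by a linear model and moderated t-tests with an intensity trend of the prior variance. P-values were adjusted by Benjamini and Hochberg's method over the 20494 probe sets, a threshold of 0.05 was used, and changes of at least 2-fold were counted separately. Fold changes are Nup98::Nsd1 over mock, and "-fold lower" gives mock over Nup98::Nsd1. Gene lists were tested with limma's camera at a preset correlation of 0.01 where at least 4 members were tested (26 of 31 lists), with adjustment over these lists, and again with the correlation estimated from the data. Il3ra was also tested by an exact permutation of its log2 signals over the 20 assignments of arrays to groups.

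Genes were named by a rule. It took Il3ra, Csf2rb, Csf2rb2, Nup98 and Nsd1, then the 12 largest rises and 12 largest falls among genes past the threshold, changed at least 2-fold, Present on all 3 arrays of the higher group and without overlap of the groups. In each list it took up to 4 members past the threshold with the smallest p, or the 2 with the largest change where none passed. Where a gene was Present on no array of the lower group, the fold was computed as a bound, with signals under the lowest Present signal of an array raised to it; where none lay under it, the fitted fold is given.

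The alternatives tried were a pseudocount of 16 or 64, no filter on detection, a filter of Present on all 6 arrays, quantile normalization, centring on the 75th percentile, the matrix of the series, no intensity trend, array quality weights, the replicate number as a block, the mean of a gene's probe sets, an estimated correlation, and leaving out each array in turn. Scaling to the hybridization controls and centring on the median of tested probe sets were added after the data were seen. The median SD of log2 signals between replicates was 0.097 in mock and 0.095 in Nup98::Nsd1 cells. On simulated data of 20494 probe sets with this design, 48%, 78%, 88% and 100% of 50 changes of log2 size 0.25, 0.5, 1 and 2 were called. Of these calls 5.42% were false. Of 26 lists simulated, the G1/S list was given a shift, and 1 list without a shift was called. The simulated noise was independent between probe sets and few of them changed, so these rates need not hold for the real data. Genome sequence and DNA copy number were not analysed here.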

Results

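Gene expression was measured in 32D cells, a mouse bone marrow line of myeloid progenitors that depends on interleukin-3 (IL-3) for growth. Of the 6 samples, 3 were mock-transduced cells, labelled with the retroviral vector MSCVpuro, and 3 carried the Nup98::Nsd1 fusion gene. The fusion occurs in acute myeloid leukaemia and joins a nuclear pore protein, Nup98, to a histone methyltransferase, Nsd1. Each sample was hybridised to 1 Affymetrix Mouse Genome 430 2.0 array of 45101 probe sets. Between 45.0% and 45.8% of probe sets were called Present on the mock arrays, against 47.5% to 48.2% on the Nup98::Nsd1 arrays. Log2 signals correlated across probe sets at r = 0.989 to 0.992 in the 6 pairs of arrays within groups and at 0.929 to 0.936 in the 9 pairs between groups; probe sets are not independent replicates. The number of arrays limits the precision, and as no label says that samples came from separate cultures, p-values measure only the spread between these samples, which could be technical.

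The series is titled for CD123, so the first question was whether its gene, Il3ra, differed between the groups. Il3ra, which encodes the alpha chain of the IL-3 receptor, was 3.29-fold higher in Nup98::Nsd1 cells. Its only probe set gave a signal of 331 ± 23.9 in mock cells and 1089 ± 82.3 in Nup98::Nsd1 cells (mean ± SD, n = 3 each; limma log2 fold change 1.72, SE 0.085, adjusted p = 1.16e-08). The mock arrays lay between 314 and 358 and the Nup98::Nsd1 arrays between 1018 and 1179, each called Present. An exact two-sided permutation test gave p = 0.1, the smallest that 3 arrays against 3 allow.

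The genes of the receptor's signalling beta chains moved far less than Il3ra. Csf2rb, the beta chain shared with the receptors for IL-5 and GM-CSF, had 2 probe sets with opposite calls. The brighter went from 4687 ± 35.9 to 5258 ± 164 (log2 fold change 0.17, adjusted p = 0.00316), a rise that turned into -0.03 with 75th percentile centring, -0.20 with hybridization control scaling and -0.0036 with median centring. The dimmer went from 2077 ± 112 to 1611 ± 58.0 (log2 fold change -0.37, adjusted p = 9.79e-05). Csf2rb2, the beta chain specific to IL-3 in the mouse, fell by 0.24 on the log2 scale, from 1839 ± 45.1 to 1563 ± 93.2 (adjusted p = 0.00241).

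The fusion partners were measured as well. Nup98 rose at both of its probe sets, by 0.47 (1389.9 ± 14.6 to 1926 ± 78.8, adjusted p = 6.19e-06) and 0.52 on the log2 scale (418 ± 70.6 to 592 ± 20.8, adjusted p = 0.0015). With hybridization control scaling the brighter stood at 0.10 and did not pass. Each of the 4 Nsd1 probe sets was called Absent on all 6 arrays, and Nsd1 was not tested. Whether these probe sets lie in the transduced sequence is not given in the sources used here, so neither gene checks the labels.

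**Figure D1:**
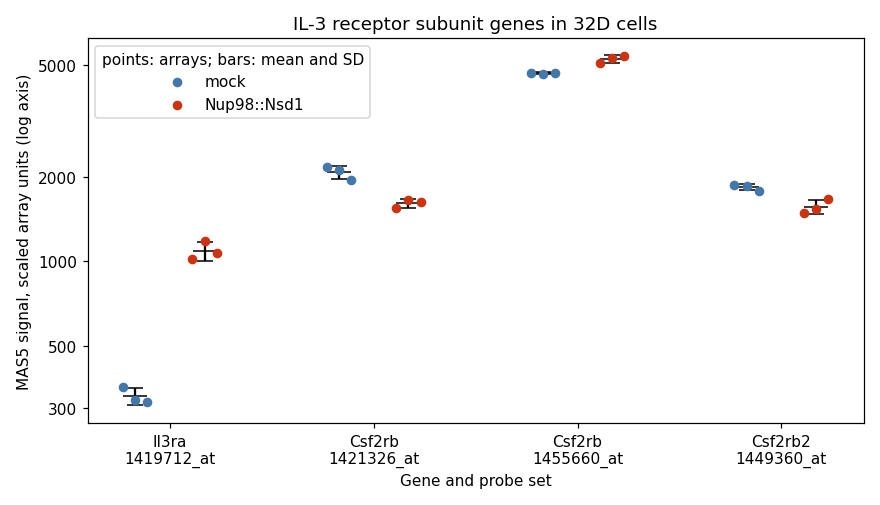
MAS5 signals (log axis, scaled array units) of the probe sets of Il3ra, Csf2rb and Csf2rb2 on each array, with points for arrays and bars for the mean and SD of 3 arrays per group. The Il3ra signals of Nup98::Nsd1 cells, from 1018 to 1179, all lie above those of mock cells, from 314 to 358, while the Csf2rb probe sets differ in direction, and the rise of the brighter is not kept with 75th percentile centring, hybridization control scaling or median centring.

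The second question was which other genes differed between Nup98::Nsd1 and mock cells. Most tested genes did: of 9641 genes, 4132 rose and 2841 fell, and at 2-fold or more 919 rose and 251 fell. Among the largest rises were those of Psrc1, a microtubule-binding protein of the spindle, Cp, the copper-carrying ferroxidase ceruloplasmin, and Abcd3, a fatty acid transporter of the peroxisome. Among the largest falls were those of Tgfbr3, the betaglycan co-receptor for TGF-beta, Kcne3, a potassium channel subunit, and Nebl, an actin-binding protein of the nebulin family.

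Psrc1 went from 10.02 ± 2.58, called Absent on every mock array, to 2541 ± 37.7, at least 241-fold higher (adjusted p = 7.9e-11). A bound of this kind sets the mean log2 signal of the higher group against, for each array of the other group, the larger of its signal and the lowest signal called Present on that array. Where every signal of the other group lay above that level, the fitted fold is given and is no bound. The level, 8.06 to 15.4 over the arrays, is no detection limit: Avil was called Absent at 64.3, 89.8 and 84.0. Under the setting that shrank each most, the log2 fold change was 5.14 for Psrc1, 1.46 for Nim1k and 1.18 for Calcrl. For Tgfbr3 it was -2.77. The words "at least" therefore hold only for the signals as deposited. Cp rose from 6.23 ± 1.99 to 629 ± 41.1, at least 69.9-fold (adjusted p = 5.06e-09). Abcd3, Present on 1 mock array, rose from 24.4 ± 1.62 to 1311 ± 46.0, or 53.7-fold (adjusted p = 6.36e-11). Slc39a8, a zinc and manganese importer that was Present on 2 mock arrays, rose 19.6-fold. Among genes Present on no mock array, Ctss, the lysosomal protease cathepsin S, rose at least 28.9-fold, and Avil, the actin-binding advillin, had a fitted rise of 21.6-fold. Kif1b, a kinesin motor, rose from 18.6 ± 22.3, Absent on each mock array at 44.4, 4.41 and 7.14, to 304 ± 52.3, and no fold is given because of that spread. Clec5a, a myeloid lectin receptor, had a fitted rise of 17.2-fold, and Nim1k, a protein kinase, rose at least 13.1-fold. Il6ra, the interleukin-6 receptor alpha chain, rose at least 13.02-fold. Asb13, a substrate receptor of a ubiquitin ligase, rose at least 10.8-fold and Calcrl, the receptor for adrenomedullin and CGRP, at least 9.67-fold.

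Tgfbr3 fell from 440.0 ± 71.6 to 9.48 ± 4.85 and was called Present on no Nup98::Nsd1 array, at least 31.2-fold lower (adjusted p = 5.35e-08). Timp2, an inhibitor of matrix metalloproteinases, had 2 tested probe sets: the brighter, Present on no Nup98::Nsd1 array, had a fitted level 11.6-fold lower, and the other a log2 fold change of -0.79. Kcne3, Present on 1 Nup98::Nsd1 array, was 11.9-fold lower. Pxk was at least 7.76-fold lower, and Svs2, a seminal vesicle protein, and Col9a3, a collagen chain, both Present on no Nup98::Nsd1 array, had fitted levels 5.89-fold and 5.81-fold lower. Khdc1a was at least 5.40-fold lower and Aif1l, an actin-bundling protein, at least 5.30-fold. Under the setting that shrank each most, their log2 fold changes were -0.86 and -1.02. Of genes still Present on all Nup98::Nsd1 arrays, Nebl was 10.5-fold lower (1941 ± 68.3 to 187 ± 40.4), and Stab1, a scavenger receptor, 7.34-fold lower. Ngp, a neutrophil granule protein, was 6.30-fold lower, and Bco1, which cleaves beta-carotene, 5.79-fold lower. By fitted change, these 24 genes were the 12 largest rises of 916 and the 12 largest falls of 250 that met the rule for naming. The rule itself required groups that did not overlap, a separation that chance alone gives in 10% of comparisons of 3 with 3.

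**Figure D2:**
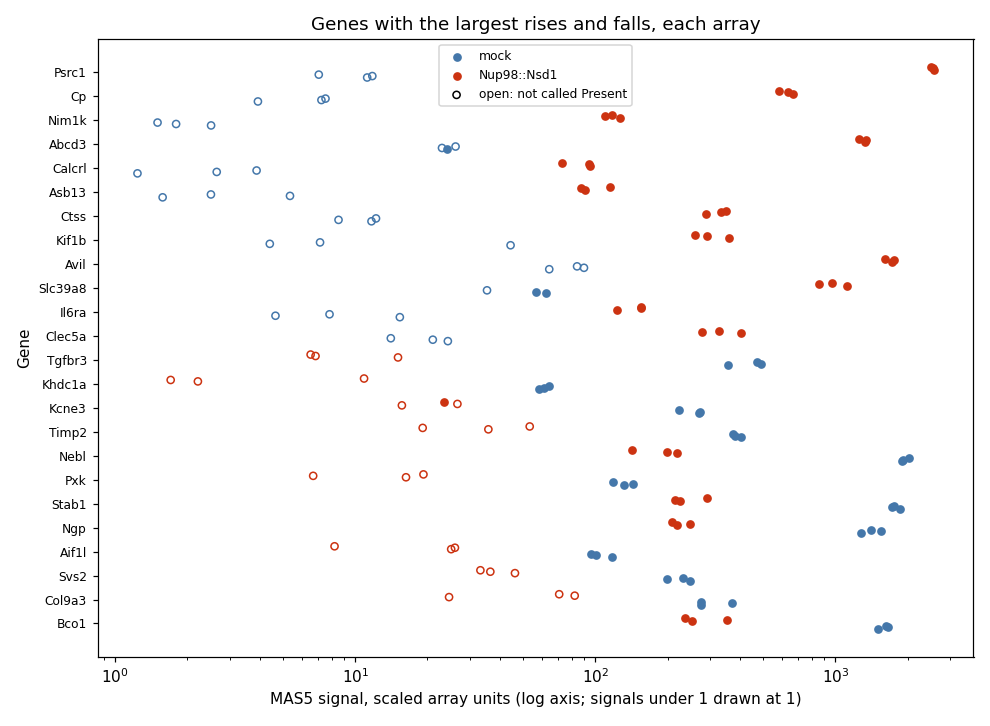
MAS5 signal (log axis, scaled array units) of the 12 genes with the largest fitted rise and the 12 with the largest fitted fall on each of the 6 arrays, with open points where the probe set was not called Present. Psrc1 averages 10.02 in mock and 2541 in Nup98::Nsd1 cells, and Tgfbr3 averages 440.0 in mock and 9.48 in Nup98::Nsd1 cells.

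Counted by probe set, 14335 of 20494 (69.9%) passed an adjusted p of 0.05 in limma, 8678 higher and 5657 lower. The share of these calls that were higher, 60.5%, was 49.7% after quantile normalization, 44.8% with 75th percentile centring, 47.1% with median centring and 32.3% with hybridization control scaling. For genes changed at least 2-fold the share was 78.5% as deposited and 66.0%, 54.1%, 57.8% and 33.2% in the same order. The median log2 fold change of tested probe sets was 0.15 as deposited, and -0.009, -0.04, -0.02 and -0.21 in that order, so a log2 fold change of 0.15 marks the middle of the tested probe sets as deposited, and each value given here includes that shift. Of 4711 genes with several tested probe sets, 598 had calls in both directions. Among genes named here as changed, Grb2, Stat5b, Pbx3, Slbp, Hmmr, Bcl2l1, Itgal, Nop16, Bop1, Wdr12 and Egln3 had at least 1 other tested probe set that was not called, and the values given are those of the brightest. Probe sets called in the same direction lay over 1 apart on the log2 scale for Timp2, Ddit3 and 5 others: Cp (4.34 to 6.71), Kif1b (2.57 to 4.75), Btg1 (0.47 to 1.81), Il2ra (0.46 to 1.59) and Tfrc (-2.66 to -1.38).

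Groups of genes fixed before the data were examined moved together in several cases. Of 26 gene lists with at least 4 tested members, 9 passed limma's camera test with a preset correlation, 4 upward and 5 downward, and 0 passed with an estimated correlation. Unadjusted p-values under 0.05 numbered 11 with the preset and 6 with the estimated correlation. Counts of members adjusted over the list alone equalled those over all probe sets for each list except the NSD, nucleoporin and chromatin regulators, of which 8 rather than 7 fell. The ratio of the 3' to the 5' control signal of Actb, a sign of RNA or labelling quality, was 1.18 ± 0.03 on mock and 1.47 ± 0.026 on Nup98::Nsd1 arrays. That of Gapdh was 0.76 ± 0.016 and 0.816 ± 0.024. Both ratios thus differed between the groups of arrays compared, and no change of a gene list can be separated from that difference.

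Inflammatory and interferon genes were higher in Nup98::Nsd1 cells. Of 15 tested NF-kB and inflammatory genes, 12 rose and 0 fell (camera adjusted p = 0.000729; adjusted p = 0.199 with an estimated correlation). The cytokine Il6 rose 4.23-fold, Nfkbia, the inhibitor that NF-kB induces, 3.16-fold, and the neutrophil chemokine Cxcl2 16.1-fold. Nfkb2, an NF-kB subunit called Present on no mock array, had a fitted rise of 4.88-fold. Of 14 tested interferon-stimulated genes, 13 rose and 0 fell (adjusted p = 0.00105; adjusted p = 0.199 with an estimated correlation). Oas1a, an antiviral enzyme Present on no mock array, had a fitted rise of 11.4-fold, the transcription factor Irf7 rose 5.41-fold, Ifi27 2.49-fold and the tetherin gene Bst2 1.88-fold.

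Of 21 tested G1/S genes, 19 fell and 1 rose (adjusted p = 2.06e-09; adjusted p = 0.089 with an estimated correlation). The helicase subunits Mcm4 and Mcm6 were 2.80-fold and 2.36-fold lower, Slbp, which binds histone mRNA, 2.43-fold lower, and the ribonucleotide reductase subunit Rrm2 2.28-fold lower. Of 22 tested G2/M genes, 16 rose and 4 fell (adjusted p = 0.11; 0.0031 after quantile normalization, the lowest of the settings tried, of which the highest was 0.633), but with hybridization control scaling 7 rose and 12 fell. The proliferation marker Mki67 rose 2.15-fold, the centromere motor Cenpe 1.81-fold and Hmmr 1.61-fold, while the mitotic kinase Aurkb was 1.58-fold lower. Of 11 cell cycle inhibitors and p53 targets, 7 rose and 2 fell (adjusted p = 0.265), which became 2 and 5 with hybridization control scaling. Cdkn1b, the inhibitor p27, rose 2.33-fold. Cdkn1a (p21), Cdkn2d and Btg1 rose by 0.45, 0.46 and 0.47 on the log2 scale and did not pass with that scaling, at 0.08, 0.10 and 0.10.

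Of 17 ribosome biogenesis and MYC target genes, 14 fell and 1 rose (adjusted p = 5.46e-05; adjusted p = 0.199 with an estimated correlation). The nucleolar genes Nop16, Nolc1, Bop1 and Wdr12 were 2.17-fold, 2.06-fold, 1.79-fold and 1.63-fold lower. Of 18 cholesterol synthesis genes, 13 fell and 2 rose (adjusted p = 0.000729; adjusted p = 0.199 with an estimated correlation). The pathway enzymes Cyp51, Sqle and Idi1 were 1.90-fold, 1.84-fold and 1.62-fold lower, and Msmo1 was 2.10-fold lower at the probe set taken for the gene and called higher at another. Of 18 glycolysis and hypoxia genes, 11 fell and 2 rose (adjusted p = 0.022; adjusted p = 0.199 with an estimated correlation), a call that quantile normalization ended (adjusted p = 0.0623, with 0.00563 the lowest of the settings tried). The glycolytic enzyme Pgam1 was 2.59-fold lower and the oxygen sensor Egln3 1.77-fold lower, while Ndrg1 and the angiogenic factor Vegfa rose 2.62-fold and 2.05-fold.

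Myeloid maturation genes went in several directions. Of 7 primary granule genes, 5 fell and 0 rose (adjusted p = 0.00393; adjusted p = 0.206 with an estimated correlation): myeloperoxidase, Mpo, was 3.68-fold lower, Ms4a3 5.13-fold, the protease gene Prtn3 1.89-fold and the protease inhibitor Cst7 1.99-fold lower. Of 10 monocyte and macrophage genes, 8 rose and 1 fell (adjusted p = 0.00638; adjusted p = 0.199 with an estimated correlation). The Fc receptors Fcgr3 and Fcgr1 rose 4.27-fold and 2.41-fold, and the lysozymes Lyz1 and Lyz2, near-identical copies whose probes could cross-hybridise, 3.24-fold and 2.75-fold. Of 13 secondary granule and mature neutrophil genes, 7 rose and 2 fell (adjusted p = 0.24), against 5 and 6 with hybridization control scaling. Lcn2, which binds bacterial siderophores, rose 7.39-fold, the neutrophil surface antigen Cd177 4.96-fold and the G-CSF receptor Csf3r 1.72-fold, while Ngp fell. Of 10 myeloid transcription factors, 5 rose and 2 fell (adjusted p = 0.388), against 2 and 4 with hybridization control scaling. Fos rose 5.96-fold and Cebpa, a regulator of granulocyte differentiation, 1.83-fold. Cebpb and Cebpd, at 0.53 and 0.44 on the log2 scale, rose as deposited and were at 0.17 and 0.08 with that scaling, no longer past the threshold.

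Markers of other blood cell types also differed. Of 7 megakaryocyte genes, 6 rose and 1 fell (adjusted p = 0.0199; adjusted p = 0.206 with an estimated correlation), a call that did not hold among probe sets Present on all 6 arrays (adjusted p = 0.0728, with 0.000292 the lowest of the settings tried). The platelet integrin chains Itgb3, Present on 2 mock arrays, and Itga2b rose 11.8-fold and 2.23-fold, platelet factor 4, Pf4, 4.83-fold, and the thrombin receptor F2r 1.58-fold. Both tested eosinophil genes fell, eosinophil peroxidase, Epx, to a level 4.65-fold lower and the surface lectin Siglecf 2.27-fold lower. Of 8 mast cell and basophil genes, 5 rose and 2 fell (adjusted p = 0.401). The IgE receptor chain Fcer1a was 5.45-fold lower, while the mast cell protease Cpa3 rose 2.03-fold and the cytokines Il6 and Il4 4.23-fold and 2.11-fold. Of 6 erythroid genes, 4 fell and 1 rose (adjusted p = 0.142): the transferrin receptor Tfrc was 2.60-fold lower, the globin gene Hba-a2, which has a near-identical copy, 1.79-fold and the transcription factor Gata1 1.51-fold lower, and Nfe2 rose 2.05-fold. Of 4 dendritic cell and MHC class II genes, 2 rose and 0 fell (adjusted p = 0.142; 0.0297 to 0.30 over the settings tried), namely Cd74, the invariant chain, 7.30-fold and Bst2 1.88-fold. Prf1, the pore-forming perforin, was the only tested T and NK cell gene and rose 2.16-fold. Neither of the 2 tested B lymphoid genes passed the threshold: Cd79b stood at a log2 fold change of -0.22 (adjusted p = 0.0688), and passed under each other scaling, from -0.39 with median centring to -0.58 with hybridization control scaling, and Vpreb1 at -0.16 (adjusted p = 0.644). Of the fibroblast genes 0 were detected well enough to be tested.

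Cytokine receptors and IL-3 signalling genes were described by lists that camera did not call. Of 13 genes of the IL-3 receptor and its signalling, 6 rose and 3 fell (adjusted p = 0.525), against 3 and 8 with hybridization control scaling, 4 and 6 with 75th percentile centring and 4 and 4 with median centring. Besides Il3ra, the adaptor Gab2 rose 2.68-fold and the transcription factor Stat5b 1.59-fold, while the adaptor Grb2 was 1.61-fold lower, with the other tested probe set of Stat5b and of Grb2 not called. Of 14 STAT5 target genes, 9 rose and 3 fell (adjusted p = 0.0799), against 6 and 6 with hybridization control scaling, and quantile normalization brought the list past the threshold (adjusted p = 0.0094, with 0.206, from the estimated correlation, the highest of the settings tried). The kinases Pim2 and Pim1 rose 3.08-fold and 1.81-fold, the IL-2 receptor alpha chain Il2ra 3.02-fold and the feedback inhibitor Cish 1.78-fold. Of 10 other haematopoietic cytokine receptors, 7 rose and 1 fell (adjusted p = 0.0758; 0.0355 to 0.206 over the settings tried, the highest with an estimated correlation): beside Il6ra, Il18r1 rose 6.38-fold, Il4ra 2.10-fold and Csf3r 1.72-fold. Of 10 MAPK feedback genes, 5 rose and 4 fell (adjusted p = 0.735), against 4 and 5 with 75th percentile centring, median centring and hybridization control scaling. Phlda1 rose 3.34-fold, the ERK phosphatases Dusp4 and Dusp6 1.83-fold and 1.52-fold, and Ier3 1.43-fold.

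Of the leukaemia-associated lists, that of 25 Hox and Meis-Pbx genes had 21 measured and 3 tested members, namely Meis1, Meis2 and Pbx3. No Hoxa or Hoxb gene of the list was tested, so the comparison gives no result for Hox genes. Of 3 tested Hox and Meis-Pbx genes, 2 rose, the Hox cofactors Meis1 by 0.64 (adjusted p = 0.00488) and Pbx3 by 0.32 on the log2 scale (adjusted p = 0.00623). Neither passed after quantile normalization, at 0.21 and 0.14, or with hybridization control scaling, at 0.28 and -0.04, and Pbx3 passed under no other scaling. Of 11 stem and progenitor genes, 6 fell and 4 rose (adjusted p = 0.265). The transcription factors Mecom and Tal1 rose 2.37-fold and 1.63-fold and Lmo2 was 1.46-fold lower. Mycn was 4.39-fold lower at the probe set taken for the gene, while its other tested probe sets were called higher. Of 15 NSD, nucleoporin and chromatin regulators, 7 fell and 6 rose (adjusted p = 0.388; median log2 fold change -0.15 and camera downward, mean 0.03), against 9 and 1 with hybridization control scaling, 9 and 4 with 75th percentile centring, 8 and 4 with median centring and 7 and 4 after quantile normalization. The methyltransferase Kmt2a rose 2.68-fold, while the nuclear export receptor Xpo1 was 1.62-fold lower and the Polycomb subunit Eed 1.40-fold lower.

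Survival, surface and stress genes completed the lists. Of 11 BCL2 family genes, 6 rose and 3 fell (adjusted p = 0.388), against 4 and 4 with hybridization control scaling. The pro-apoptotic Bbc3 (Puma) and Bmf rose 4.48-fold and 2.67-fold and the anti-apoptotic Bcl2l1 1.76-fold at 1 of its 3 tested probe sets, the others not called, while the pro-apoptotic Bid was 1.41-fold lower. Of 13 adhesion and homing genes, 7 rose and 2 fell (adjusted p = 0.489), against 5 and 6 with hybridization control scaling and 75th percentile centring. The integrin chain Itgal and the adhesion molecule Icam1 rose 1.89-fold and 1.72-fold, and the integrin chain Itgb1 and the marrow homing receptor Cxcr4 were 2.37-fold and 2.14-fold lower. Of 15 unfolded protein and amino acid response genes, 8 rose and 5 fell (adjusted p = 0.401), against 5 and 7 with hybridization control scaling. Ddit3, the stress transcription factor CHOP, rose 15.9-fold from 425 ± 24.6 to 6752 ± 85.1 at its brighter probe set (log2 fold change 3.99, against 1.32 at the other), and Trib3, a pseudokinase that CHOP induces, 15.4-fold from 434 ± 25.1 to 6685 ± 231. Herpud1 rose 2.11-fold and Sdf2l1, an endoplasmic reticulum protein, was 3.19-fold lower. Of 7 heat shock and immediate-early genes, 4 rose and 3 fell (adjusted p = 0.999), with a positive median and mean (0.20 and 0.40) and a downward camera direction, and 3 and 4 with hybridization control scaling. The immediate-early Fos and Dusp1 rose 5.96-fold and 2.36-fold, while the chaperones Hsph1 and Dnajb1 were 2.09-fold and 1.42-fold lower.

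**Figure D3:**
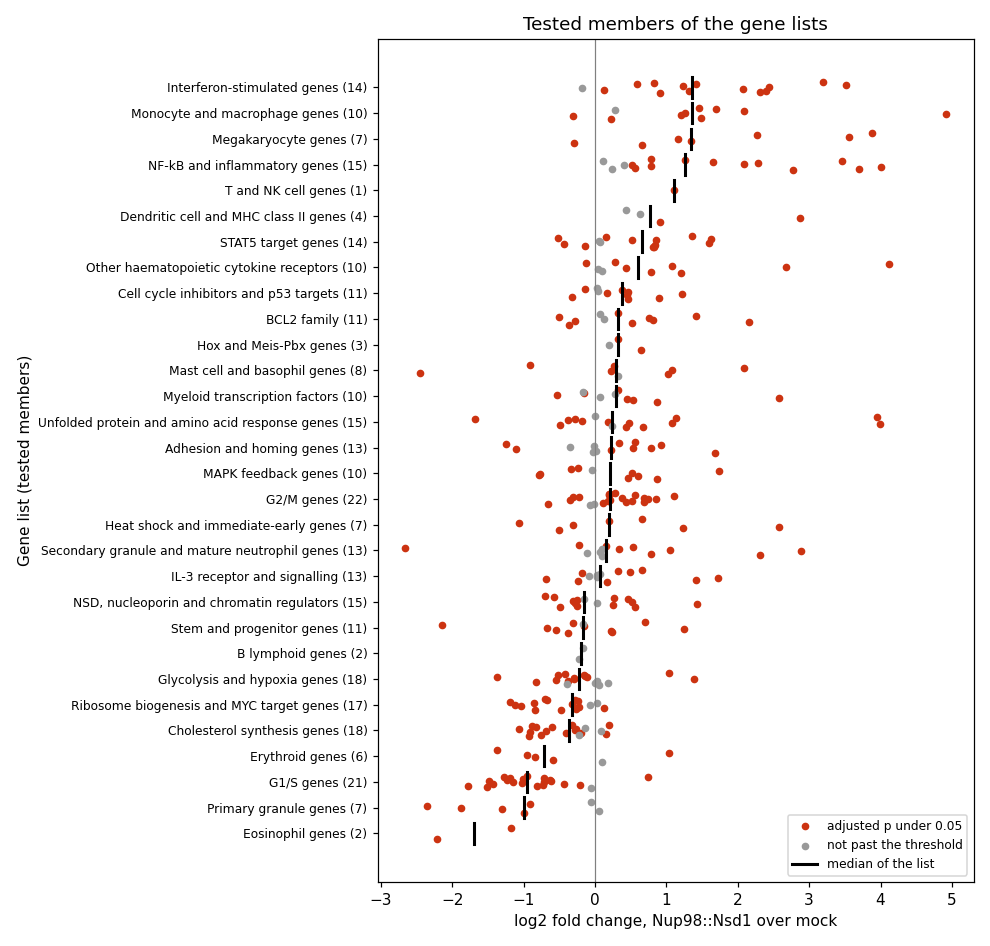
Log2 fold change (Nup98::Nsd1 over mock) of each tested member of the gene lists, with lists ordered by their median (black bar) and points in red where the adjusted p was under 0.05. Of 21 tested G1/S genes, 19 fell, and of 14 interferon-stimulated genes, 13 rose, and these majorities kept their direction under each scaling tried.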

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

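The test of array scaling in this part was chosen only after the result was seen; the tests of undetected probe sets and of other splits were set beforehand. Of the control probe sets that the comparisons leave out, the poly-A controls did not separate the groups (log2 means 8.56 ± 0.57 in mock and 9.18 ± 0.10 in Nup98::Nsd1 cells). Each of the other 4 measures was higher on all 3 Nup98::Nsd1 arrays than on all 3 mock arrays, a separation that chance gives, in either direction, in 10% of comparisons of 3 with 3. Hybridization controls, transcripts added with the labelled sample, were higher by 0.37 on the log2 scale (12.18 ± 0.07 in mock and 12.54 ± 0.014 in Nup98::Nsd1 cells, mean ± SD, n = 3). The 3' to 5' ratio of Actb was higher by 0.31 on the log2 scale, and that of Gapdh by 0.10. The control for the B1 repeat, a short interspersed element found throughout the mouse genome, was higher by 0.85, with signals of 1038 ± 77.2 and 1869 ± 112.

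More probe sets were called higher than lower, 8678 against 5657. With arrays scaled to the hybridization controls the share of calls that were higher fell from 60.5% to 32.3%, so the imbalance depended on the choice of scaling. That scaling lowers every log2 fold change by the 0.37 of these controls, more than the median of 0.15. A fall of the share therefore followed from the control values. Probe sets called Absent on all 6 arrays also had a positive median log2 difference, 0.22 over 19115, against 0.10 over the 17905 Present on all 6. A lift of signals unrelated to expression may therefore account for part of the imbalance, and a difference in RNA content per cell, which was not measured, stays open beside it. No biological explanation beyond the group label was tested.

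The 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. For probe sets changed, genes changed and genes changed at least 2-fold, 1 of the 10 splits, the real one, gave the real count of 14335, 6973 and 1170, and the highest of the other splits was 0 for each. Each other split mixes mock and Nup98::Nsd1 arrays in both of its groups, which widens the spread within groups, so a count of 0 there says little. For gene lists called it was again 1 of 10, with 9 lists in the real split and 3 to 7 in the others, where 0 genes changed.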

How the results depend on the processing

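Scaling to the hybridization controls and median centring were chosen only after the result was seen. Il3ra kept its direction and its side of the threshold in all 18 alternatives run, with log2 fold changes from 1.35 (hybridization control scaling) to 1.78, and from 1.66 to 1.78 when each array was left out. Of 76 counts, 75 stayed within 1.5 times the value reported. The exception was the number of gene lists called, 0 of 26 with an estimated inter-gene correlation against 9; the cause was not tested. Without each array in turn, probe sets changed ranged from 13463 to 13954, genes changed from 6553 to 6764, genes changed at least 2-fold from 1155 to 1190, and lists called stayed at 9.

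Counts by direction depended on scaling: with the hybridization controls the probe sets changed were 4573 higher and 9586 lower, and among genes changed at least 2-fold 423 were higher and 853 lower. Replicate numbers gave no sign of pairing, with correlations of deviations between arrays of the same number of -0.017, -0.011 and 0.021; a replicate block gave 14257 probe sets changed, 6941 genes changed, 1172 genes changed at least 2-fold and 9 lists.

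Of the comparisons of gene lists with their alternatives, 489 kept direction and side of the threshold, 8 came past it, 11 no longer passed and 11 reversed; for named genes these were 2259, 5, 11 and 5. The heat shock and immediate-early list, downward by camera with an adjusted p of 0.999, changed its camera direction to upward, while its mean difference from other genes, 0.23 as reported, was positive throughout: 0.26 with Present on all 6 arrays, 0.28 with quantile normalization, 0.24 with array quality weights, and 0.23 with 75th percentile centring, replicate block, hybridization control scaling and median centring. Without single arrays that difference lay between 0.21 and 0.26. The IL-3 receptor and signalling list stood at 0.032 and turned downward by camera with the mean of all tested probe sets. Csf2rb turned to -0.030 with 75th percentile centring, -0.20 with hybridization control scaling and -0.0036 with median centring, and Pbx3 to -0.044 with hybridization control scaling. Vpreb1, at -0.16, ranged from -0.36 to 0.080 when each array was left out, the latter without Nup98::Nsd1 replicate 3, and its lowest value in all settings was -0.53. Shifts of the scalings move every gene of an array alike, except under quantile normalization; for the other reversals the cause was not tested. Signal over background limited the tests to 20494 of 45037 probe sets.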

Other observations

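The tests of chance concentration and of dosage on chromosomes 7 and 3 and the test of neighbouring genes were chosen only after the result was seen. Genes named in this part were chosen after their values were seen.

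Enzymes that load amino acids onto tRNA, many of them targets of the amino acid response that also induces Ddit3 and Trib3, were tested as a hypothesis. Sars, whose value had already been seen beside Psrc1, was left out. Of 18 other cytosolic synthetase genes, 13 rose and 4 fell, with a median log2 fold change of 0.26, among them Vars at 1.10, Cars at 1.06, Aars at 1.04 and Farsa at -0.79. Of 15 mitochondrial synthetase genes, 3 rose and 3 fell, with a median of 0.045. The medians differed by 0.21, with a permutation p of 0.0569, which missed the threshold of 0.05 set beforehand. By the rule set beforehand, a p of 0.05 or more counted against the hypothesis, as a difference under 0.1 would have. The difference lay in the predicted direction and above 0.1, which does not offset the p. An amino acid response was therefore not shown, and a p this near the threshold does not exclude it.

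Genes of chromosome 7 (GRCm38.p6 map) were higher as a set. Their median log2 fold change was 0.44 over 731 genes, against 0.09 for genes of other chromosomes, in 9 of 9 pairs of arrays, and the shift after quantile normalization was 0.30. Against random gene sets of the same size the permutation p was 1e-04, the smallest that 10000 draws can give (0.000667 adjusted over the 20 chromosomes); this test singled the chromosome out and treats genes as independent, so it excludes only a random placement of genes. Genes above the median signal had a shift of 0.36, which argues against low signals. All 10 bins of the chromosome's genes in map order had a median above the other chromosomes' genes, so an extra copy of chromosome 7 in the Nup98::Nsd1 cells may be a candidate explanation. DNA copy number was not measured, genes are not replicates, and an effect of the fusion on these genes was not tested. Values given above for single genes, Nup98 and Il3ra included, were not corrected for any shift of the chromosome they lie on.

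Genes of chromosome 3 were higher as well, with a median of 0.41 over 459 genes against 0.10 elsewhere, in 9 of 9 pairs of arrays, and a shift of 0.35 after quantile normalization. The same permutation p was 1e-04, again the smallest possible (0.000667 adjusted), with the same limits, and genes above the median signal had a shift of 0.30, which argues against low signals. Only 7 of 10 bins lay above the other chromosomes' genes, from a highest shift of 0.80 to -0.16 ± 0.053 (bootstrap SE), so dosage of the whole chromosome is argued against. A gain of parts of it may still be open and was not tested. Of 20 chromosomes 7 differed from the rest at an adjusted p under 0.05; beside 7 and 3 the next highest shift was 0.12 on the X chromosome, and the lowest was -0.19 on chromosome 12. Chromosome 14, with a shift of 0.04 (adjusted permutation p = 0.508), was also higher in 9 of 9 pairs of arrays. The pairs reuse the same arrays, so that count says little for chromosomes 7 and 3.

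Activation spreading from the genes with the largest rise to their neighbours was tested too. The 24 nearest tested neighbours of the 12 genes had a median absolute log2 difference of 0.51, against 0.39 for neighbours of random genes. The permutation p of 0.131 did not pass the threshold, so spreading was not shown. The random genes were not matched by chromosome, and genes of chromosomes 7 and 3 were higher as sets. How many of the 12 genes and their neighbours lie on these chromosomes was not counted. The test therefore cannot separate spreading from such shifts, which leaves the hypothesis undecided. Beside Psrc1, Sort1 stood at a log2 fold change of 2.63 and Sars at 1.81.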
